A study of Capra hircus with 40 samples.

How the data were processed

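Small RNA was sequenced from the ovary and the uterus of Jining gray goats at 4 ages, day 1 and months 2, 4 and 6 after birth. Each of the 8 groups of tissue and age held 5 libraries from separately numbered individuals per the labels, 40 libraries in all. The labels do not say whether an ovary and a uterus with the same number came from the same goat, and the numbers start again at each age, so all libraries were treated as independent. Sequencing batches, dates and lanes are not given.

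The deposited table holds read counts per mature miRNA and library, produced by the authors without normalization; all values are whole numbers. The processing notes of the authors name cutadapt 1.16, Bowtie 1.0.1 and RSEM 1.3.0, with no role or order. The genome build, the miRNA annotation and the adapter settings are not stated, so no positions are given. Names carry the goat prefix, which is left out in the text. The table lists 427 miRNAs, of which 16 are let-7 and 411 are miR entries, and some entries give no arm. Library totals ran from 5502588 to 8442089 counts. How reads that match several paralogs were assigned is not stated, so the split of signal among let-7 members, miR-200b, miR-200c and miR-429, miR-199a and miR-199b, or miR-1 and miR-206 is uncertain.

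Counts were analysed in R 4.3.3 with edgeR 4.0.16. The ovary libraries, the uterus libraries and all 40 libraries were fitted apart, with the group of tissue and age as the factor. filterByExpr kept 317 miRNAs in the ovary fit, 331 in the uterus fit and 350 in the joint fit. Trimmed mean of M values (TMM) scaling was applied, and the quasi-likelihood test of edgeR gave log2 fold changes and two-sided p-values. The p-values were adjusted by the Benjamini-Hochberg method over all miRNAs tested in a comparison, and an adjusted p under 0.05 counted as a call. The test gives no standard error (SE). It was derived from each log2 change as its absolute value divided by the square root of the F statistic of the test. The common biological coefficient of variation was 0.624 in ovary, 0.598 in uterus and 0.628 in the joint fit. Adjusted p-values of single miRNAs in the text are from edgeR unless another tool is named. Levels are counts scaled to the library total (CPM), given as mean ± SD with n = 5 libraries per group. Log2 CPM, used for principal components, correlations of libraries and mean levels of lists, differs from these. It takes in the TMM factors of the joint fit and a prior count of 2. Log2 changes are given ± SE, with 5 libraries per group.

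There were 16 comparisons. Within each tissue, month 2 was compared with day 1, month 4 with month 2, month 6 with month 4, and month 6 with day 1. Uterus was compared with ovary at each age and over the 4 ages together. Interaction terms compared the age change in uterus with that in ovary for the 3 successive steps. Overlaps of the calls of both tissues were tested with Fisher's exact test, across miRNAs, which are not independent replicates.

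There were 19 lists of miRNAs. They were the let-7 family, the miR-17-92 cluster and its paralogs, the miR-200 family and the miR-183-96-182 cluster of epithelium, and the miR-34/miR-449 family of ciliated epithelium. Others were the miR-143/miR-145 cluster of smooth muscle, striated muscle miRNAs, gonad and granulosa cell miRNAs, pluripotency miRNAs, the DLK1-DIO3 imprinted cluster, the X-linked miR-424/miR-503 cluster and HOX-embedded miRNAs. The rest were the miR-29 family, miR-199/miR-214 of fibroblasts and stroma, and endothelial, red blood cell, leukocyte, neural and neuroendocrine, and liver miRNAs. Lists with 3 or more members tested were compared with all other miRNAs by camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the data and fry were run beside it. A count "adjusted over the list alone" uses the p-values of the members only.

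The miRNAs named in the text were chosen by a rule. In each age comparison and in the tissue comparison over the 4 ages, the 10 largest changes in each direction were taken among calls with a mean of at least 10 CPM. For single ages and interactions, 5 in each direction were taken. List members and the 10 most abundant miRNAs of each tissue were added. The comparisons, tests, lists, naming rule and alternative settings were fixed before the data were examined.

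The alternative settings were DESeq2 size factors, library totals alone, no low-count filter, a stricter filter of at least 10 CPM in at least 5 libraries, the Wald test of DESeq2 1.42.0, the replicate number as a block, only the compared groups in the fit, and each replicate left out in turn. After the data were seen, 5 libraries that stood apart were left out, and then these with another 2 doubted libraries, 7 in all. Later still, single libraries were left out in turn for the miR-202 ratios between the tissues and for the miR-200 family test in uterus at month 6 against month 4. The pipeline was tested on simulated data with 200 changed miRNAs. Counts were drawn with the trended dispersions of the fit, with equal group means apart from the set changes and no outlying libraries. Recovery in the real data may therefore be lower. In ovary at month 2 against day 1 the pipeline recovered 69.7% of simulated 4-fold and 17.9% of 2-fold changes, and in the tissue comparison over the 4 ages 97.0% and 77.6%. For month 4 against month 2 and month 6 against month 4, recovery of 2-fold changes was 10.4% and 16.4% in ovary. In uterus it was 20.9% and 25.4%. A count of 0 at these steps therefore does not show that levels were stable. For the interactions the pipeline recovered between 6.06% and 31.8% of 4-fold changes, so small counts of interactions carry little weight.

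For a miRNA with no count in a group, the fold is a lower bound against a floor of 3 counts over the group. With a few counts, the ratio of pooled shares is given with an exact 95% counting interval. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Correlations across libraries were tested with 100000 permutations, two-sided. Groups of 5 were searched for single distant libraries with Dixon's ratio and a critical value of 0.71. Each count of calls was compared with 100 splits of the same libraries into groups of the same sizes, the real split included. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out of the values reported as the main result, and no genome sequence or mature miRNA sequence was at hand, so sequence composition was not examined.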

Results

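Mature miRNAs were counted in ovary and uterus of Jining gray goats, a breed whose sexual maturation the study followed from birth, at day 1 and at months 2, 4 and 6. The 40 libraries formed 8 groups of 5 individuals. Totals ran from 7539848 to 8405361 counts in ovary at day 1, from 5719892 to 7387622 at month 2, from 5889079 to 6897802 at month 4 and from 6316644 to 8017302 at month 6. In uterus they ran from 7005651 to 8442089 at day 1, from 7459887 to 8149915 at month 2, from 5502588 to 7810745 at month 4 and from 7026495 to 7835510 at month 6. Ovary libraries at day 1 held 383 ± 10.4 detected miRNAs (mean ± SD, n = 5) and uterus libraries at day 1 held 385 ± 1.67, against 360 ± 7.30 and 369 ± 10.2 at month 2.

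The smooth muscle miRNA miR-143-3p had the highest mean share of counts in both tissues, 12.9% ± 14.8 in ovary and 17.7% ± 7.89 in uterus (SD, n = 20). It was the most abundant miRNA in 14 of the 20 uterus libraries but in only 4 of the 20 ovary libraries, where let-7a-5p led in 8. In ovary the next mean shares were those of miR-99a-5p at 7.77% ± 2.71, miR-148a-3p at 7.08% ± 6.67 and let-7a-5p at 6.65% ± 3.97. In uterus it was followed by miR-10b-5p, encoded within a HOX gene cluster, at 9.48% ± 4.05, and by let-7a-5p at 6.23% ± 4.00. The principal component with the most variance (37.2%) set the day 1 libraries of both tissues apart from later ages, and the next (17.7%) ran between the tissues without parting them. On it the uterus libraries lay between -14.5 and -0.342 and 17 of the ovary libraries above 0, while ovary month 4 replicates 3 (-2.58) and 4 (-4.87) and ovary month 6 replicate 1 (-6.79) lay within the uterus range. Uterus month 2 replicate 1 lay among the day 1 uterus libraries. Ovary day 1 replicate 3 held 73.3% of its counts in miR-143-3p.

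**Figure D1:**
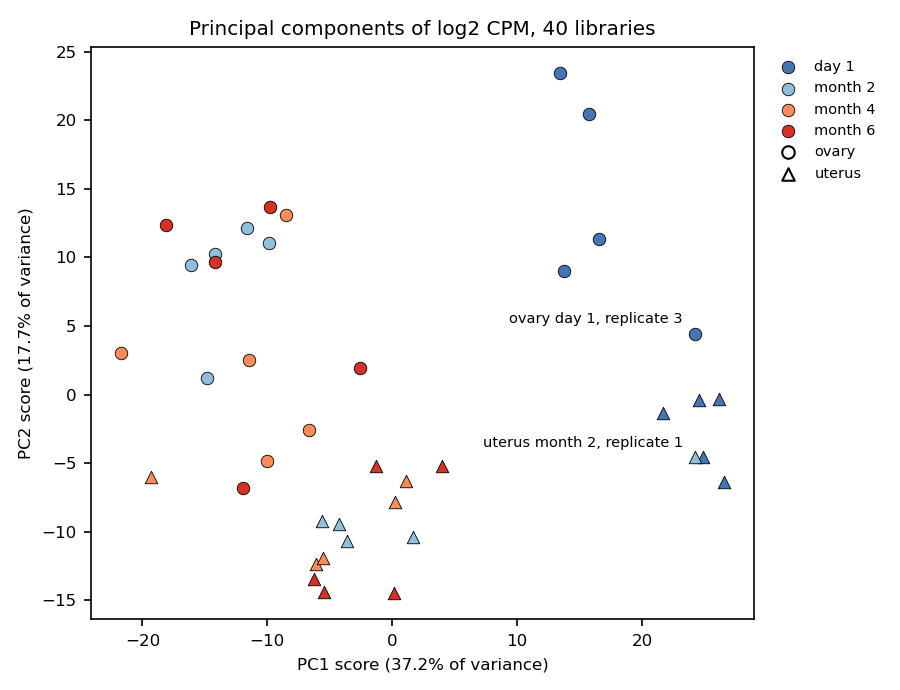
Scores of the 40 libraries on the principal components PC1 (37.2% of variance) and PC2 (17.7%) of log2 CPM, coloured by age, with circles for ovary and triangles for uterus. Day 1 libraries lie to the right together with uterus month 2 replicate 1.

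Another 5 libraries, called the 5 libraries that stand apart below, were ovary month 6 replicates 2 and 4, uterus month 4 replicate 4, and uterus month 6 replicates 4 and 5. Their let-7a-5p levels were 15864.5 to 28359 CPM, in the range of day 1 (3100 to 39214 CPM) and, apart from uterus month 2 replicate 1 at 27683 CPM, below the 46127 to 122967 CPM of the other later libraries. Their let-7b-3p levels were 1198 to 2489 CPM, against at most 419 CPM in the 35 others. These 5, with uterus month 2 replicate 1 and ovary day 1 replicate 3, are the 7 doubted libraries. Uterus month 2 replicate 1 correlated at a mean rho of 0.965 with the day 1 uterus libraries and 0.900 with its own group. Whether the labels and tissue pieces of these last libraries are right is the doubt and was not settled; both enter all values unless their removal is stated.

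Between day 1 and month 2 the ovary exchanged much of its miRNA profile. The let-7 family, whose members repress growth genes and accumulate as tissues mature, rose in 5 of 9 members: let-7a-5p went from 20392 ± 12849 to 89458 ± 18842 CPM, a log2 change of 1.97 ± 0.52 (adjusted p = 0.00341, higher in all 5 month 2 libraries than in any day 1 library). let-7b-5p (2.53 ± 0.59), let-7c-5p (1.95 ± 0.63), let-7d-5p (1.98 ± 0.47) and let-7e-5p (2.01 ± 0.59) rose with it, miR-98-5p fell by 1.09 ± 0.34, a call lost when only library totals scaled the counts, and let-7f-5p was at 0.16 ± 0.32. Adjusted over the list alone, 5 members also rose and 1 fell, and the family as a set was not called (camera adjusted p = 0.277). The largest rises were miR-125a-3p (3.15 ± 0.49, 8.88-fold), miR-1343 (2.86 ± 0.43), miR-92a-3p (2.74 ± 0.46) and miR-423-5p (2.70 ± 0.37). The largest falls were miR-136-3p (-5.21 ± 0.76, from 202 ± 59.2 to 7.71 ± 3.09 CPM), miR-202-5p (-4.74 ± 1.05), miR-218 (-4.30 ± 0.76), miR-19b-3p (-4.22 ± 0.80) and miR-424-5p (-3.96 ± 0.72). Without ovary day 1 replicate 4, which held 7818 CPM, the fall of miR-202-5p was -3.54, and without ovary day 1 replicate 3 that of miR-218 was -2.75.

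Of 41 members of the DLK1-DIO3 cluster, an imprinted locus active in fetal and placental growth, 20 fell and 5 rose in ovary from day 1 to month 2, over all miRNAs and adjusted over the list alone. Examples were miR-411a-5p (-3.33 ± 0.53), miR-369-3p (-3.51 ± 0.47) and miR-379-5p (-1.95 ± 0.48). The set was called lower (camera adjusted p = 0.0463), with adjusted p = 0.856 with an estimated correlation. In the miR-17-92 cluster and its paralogs, known to promote proliferation, 6 of 10 members fell and 2 rose (camera adjusted p = 0.669, with the same counts adjusted over the list alone). Its miR-92a-3p rose from 3887 ± 2359 to 29342 ± 7301 CPM, while miR-19b-3p, made from the same transcripts, fell. In the miR-424/miR-503 cluster, 4 of 6 members fell and miR-424-3p rose (1.64 ± 0.49; camera adjusted p = 0.277). Among 7 gonad and granulosa cell miRNAs, 3 rose, with miR-320-3p at 2.39 ± 0.38, and 2 fell, miR-202-5p and miR-21-5p (-2.94 ± 0.68). The median of this list was 0.89, its mean was -0.18 and its test was not called (camera adjusted p = 0.669). The endothelial miR-126-5p (-3.12 ± 0.45) and the red blood cell miR-451-5p (-2.73 ± 0.69) fell, and the lymphocyte miR-150 rose (2.34 ± 0.56). Without ovary day 1 replicate 3 the values of miR-451-5p and miR-21-5p were -1.22 and -2.09, and without ovary month 2 replicate 2 that of miR-150 was 1.72, all still called.

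The question of that comparison was what changed in ovary between birth and month 2, and of 317 miRNAs tested 182 were called, 79 higher and 103 lower. Without the 5 libraries that stand apart the count was 198, and without the 7 doubted libraries 192. The median change of all miRNAs was -0.16, and 0.17 with library totals alone, which gave 87 higher and 66 lower, so directions are relative to this median. The 5p and 3p arms of a hairpin, made from the same transcript, often parted: over 98 hairpins (without miR-202) the median difference between arms was 1.23 on the log2 scale, against 0.255 to 0.603 between the tissues at single ages. The difference was not scaled to the changes, whose median absolute mean of both arms was 0.966, against 0.386 to 0.819 between the tissues. From month 4 to month 6 the difference was 0.367 in ovary and 0.386 in uterus, with smaller mean changes of 0.264 and 0.205. In miR-424 the 5p arm fell and the 3p arm rose, and miR-202-3p rose by 2.01 ± 0.84 while miR-202-5p fell, the former call being lost without any of 6 single libraries: ovary day 1 replicates 1, 2 and 5 and month 2 replicates 2, 3 and 5.

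**Figure D2:**
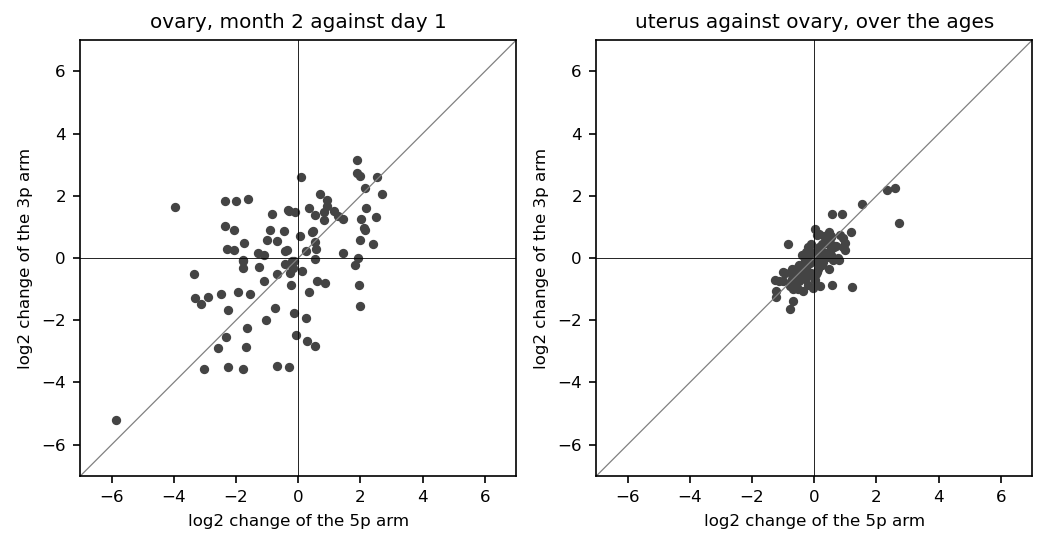
Log2 change of the 3p arm against that of the 5p arm of each hairpin, in ovary at month 2 against day 1 (left, 98 hairpins) and in uterus against ovary over the 4 ages (right, 113 hairpins). Points are hairpins and the diagonal marks equal change. The median difference between arms was 1.23 on the left and 0.278 on the right, not scaled to the size of the changes. The median absolute mean of both arms was 0.966 on the left and 0.436 on the right.

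Over the whole span from day 1 to month 6, the ovary gained let-7b-3p (5.74 ± 0.78), miR-328-3p (3.85 ± 0.47), miR-129-3p (3.65 ± 0.41) and miR-125a-5p (2.87 ± 0.54, from 7376 ± 5646 to 50375 ± 17405 CPM). Without the 5 libraries that stand apart let-7b-3p was at 3.61, miR-328-3p at 2.95 and miR-129-3p at 2.93, and without the 7 doubted libraries miR-125a-5p was at 2.25. The lymphocyte miR-150 went from 43.3 ± 18.5 to 451 ± 168 CPM (3.21 ± 0.58, adjusted p = 0.000186, higher in all 5 libraries). The largest falls were miR-202-5p (-4.87 ± 1.06, from 2316 ± 3165 to 74.0 ± 42.6 CPM, and -3.56 without ovary day 1 replicate 4), miR-424-5p (-4.36 ± 0.74) and miR-369-3p (-3.69 ± 0.48). In the DLK1-DIO3 cluster 25 of 41 members fell and 0 rose, the same numbers as adjusted over the list alone, with miR-411a-5p at -3.13 ± 0.53 and miR-379-5p at -2.49 ± 0.49. That set was called lower (camera adjusted p = 5.08e-06), with adjusted p = 0.955 with an estimated correlation.

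In the miR-424/miR-503 cluster 5 of 6 members fell from day 1 to month 6 in ovary (camera adjusted p = 0.0469). That set call was lost without the 5 libraries that stand apart and with library totals alone, and had adjusted p = 0.955 with an estimated correlation. Of 10 members of the miR-17-92 cluster and its paralogs 7 fell, among them miR-363-3p (-2.63 ± 0.38), and miR-92a-3p rose by 2.85 ± 0.47. Adjusted over the list alone 7 fell and 2 rose. In the let-7 family 4 of 9 members rose, let-7a-5p by 1.79 ± 0.52, and 2 fell, miR-98-5p and let-7i-5p (-0.83 ± 0.29), both lost without the 5 libraries that stand apart. Of 317 miRNAs 167 were called, 74 higher and 93 lower. Without the 5 libraries the count was 184, and without the 7 doubted libraries 189.

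From month 2 to month 4 the ovary showed its clearest shift in the miR-29 family, known to repress collagen genes. Its 5 tested members had a median log2 change of 0.98, and 4 of them rose adjusted over the list alone, with miR-29b-3p going from 2.52 ± 1.90 to 12.95 ± 2.86 CPM (2.44 ± 0.63, higher in all 5 libraries) and miR-29a-3p at 0.88 ± 0.40. The set was called higher (camera adjusted p = 3.6e-05), also with adjusted p = 0.0249 with an estimated correlation. The miR-34/miR-449 family of ciliated epithelium had a median of 3.09 (camera adjusted p = 0.0179) and the miR-200 family of epithelium a median of 2.87 (camera adjusted p = 0.0390), both with adjusted p = 0.446 with an estimated correlation. miR-200b spanned 154 to 38355 CPM among the ovary libraries of month 4 alone, and the miR-200 call was lost with DESeq2 size factors and without the 5 libraries that stand apart. The miR-424/miR-503 cluster (median -0.64, camera adjusted p = 0.0147) and the miR-17-92 cluster and its paralogs (median -0.37, camera adjusted p = 0.0390) were called lower, again with adjusted p = 0.446 with an estimated correlation, and the miR-17-92 call was lost with library totals alone. No single miRNA passed: the edgeR count was 0 over all miRNAs, with 31 at an unadjusted p under 0.05, 1 by DESeq2 and 1 with only the groups compared in the fit. The count without the 5 libraries was 0, and without the 7 doubted libraries 2. Leaving out ovary month 2 replicate 4 gave 1.

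From month 4 to month 6 in ovary, the DLK1-DIO3 cluster had a median log2 change of -0.79 over 41 members (camera adjusted p = 5.4e-07, and adjusted p = 0.520 with an estimated correlation). The let-7 family had a median of -0.41 (camera adjusted p = 0.0399, and adjusted p = 0.520 with an estimated correlation). Without the 5 libraries that stand apart, which include 2 of the 5 month 6 ovary libraries, the mean of the let-7 family turned to 0.0905, and the call was also lost with library totals alone. No miRNA passed the edgeR test (0 called, 37 at an unadjusted p under 0.05, 1 by DESeq2), and the counts without the 5 or the 7 libraries were 0 as well.

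In uterus from day 1 to month 2, the lymphocyte miRNA miR-150 went from 41.3 ± 13.04 to 333 ± 209 CPM (2.94 ± 0.43, adjusted p = 0.000401, higher in all 5 libraries), and miR-155-5p, known from activated lymphocytes, rose by 1.71 ± 0.45. Of 7 leukocyte miRNAs 3 rose and 0 fell, also adjusted over the list alone. The list was called higher by fry (adjusted p = 0.000768), which asks only whether its members changed, in a comparison that called 27.5% of all miRNAs. It was not called by camera, which compares it with all other miRNAs (adjusted p = 0.348). let-7a-5p rose from 19510 ± 3015 to 73978 ± 27700 CPM (1.88 ± 0.43), let-7b-5p by 2.07 ± 0.47 and let-7d-5p by 1.60 ± 0.37. In all, 4 of 9 let-7 members rose, 5 adjusted over the list alone, and the family was not called (camera adjusted p = 0.20045). Other large rises were miR-193b-5p (2.63 ± 0.57), miR-92a-3p (2.45 ± 0.49), miR-424-3p (2.34 ± 0.44), miR-125a-5p (2.31 ± 0.47) and miR-320-3p (2.18 ± 0.36).

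The largest falls in uterus from day 1 to month 2 were miR-141 of the miR-200 family (-2.65 ± 0.87), miR-542-3p (-2.60 ± 0.70), miR-340-5p (-2.51 ± 0.68) and miR-21-5p (-2.42 ± 0.54, from 29167 ± 14127 to 5031 ± 4767 CPM). The call of miR-141 was lost without uterus month 2 replicate 2, 3, 4 or 5. Without uterus month 2 replicate 1 these falls were larger, at -3.84, -3.47, -3.23 and -3.41. In the smooth muscle cluster miR-145-5p rose by 1.31 ± 0.28 and miR-143-5p fell by 1.17 ± 0.32 (camera adjusted p = 0.715 for its 4 members). In the DLK1-DIO3 cluster 9 of 44 members fell and 3 rose, and 11 and 4 adjusted over the list alone (camera adjusted p = 0.180). Of 331 miRNAs 91 were called, 56 higher and 35 lower. The split was 56 and 57 with DESeq2 size factors, and 60 and 58 with library totals, while 137 were called with no filter, 143 by DESeq2 and 141 with only the groups compared. Leaving out uterus month 2 replicate 1, which resembled day 1, gave 188; 141 were called without the 5 libraries that stand apart, and 209 without the 7 doubted libraries.

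By month 6 the uterus had gained let-7b-3p (6.06 ± 1.21, and 3.38 without the 5 libraries that stand apart), miR-193b-5p (4.18 ± 0.61), miR-197-3p (3.99 ± 0.67, from 55.1 ± 12.1 to 796 ± 637 CPM) and miR-150 (3.46 ± 0.44) against day 1. miR-145-5p, a miRNA of smooth muscle, rose by 1.68 ± 0.28, from 9155 ± 2380 to 28832 ± 6946 CPM (adjusted p = 0.000143, higher in all 5 libraries). miR-193b-5p was at 3.49 and miR-197-3p at 2.71 without the 5 libraries. let-7a-5p rose by 1.85 ± 0.43, and 3 of 9 let-7 members rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.870). The largest falls were miR-542-3p (-2.59 ± 0.70), miR-708-5p (-2.47 ± 0.72) and miR-136-3p (-2.60 ± 1.04), the last call being lost without any of 5 libraries: uterus day 1 replicates 2 and 4 and month 6 replicates 2, 3 and 4. In the DLK1-DIO3 cluster 15 of 44 members fell, with miR-379-5p at -1.40 ± 0.28 and miR-411a-5p at -1.86 ± 0.53, and 6 rose, with miR-433 at 2.06 ± 0.61 and miR-485-5p at 1.71 ± 0.43. These counts were the same adjusted over the list alone, and the set was not called (camera adjusted p = 0.0816). Of 11 tested members of the miR-17-92 cluster and its paralogs 2 rose, with miR-92a-3p at 3.25 ± 0.51 (2.43 without the 5 libraries), and 3 fell. Of 331 miRNAs 155 were called, 90 higher and 65 lower, 185 without the 5 libraries and 217 without the 7 doubted libraries. With DESeq2 size factors 82 were higher and 89 lower, and the median of all miRNAs moved from 0.04 to -0.14.

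Between month 2 and month 4 in uterus, the DLK1-DIO3 cluster had a median log2 change of -0.38 over 44 members (camera adjusted p = 0.0259, and adjusted p = 0.760 with an estimated correlation). No miRNA passed in edgeR, with 0 called, 61 of 331 at an unadjusted p under 0.05, 12 by DESeq2 and 1 with the stricter filter, and counts of 0 without the 5 and without the 7 libraries. Leaving out uterus month 2 replicate 4 gave 1. From month 4 to month 6 in uterus, the miR-200 family of epithelium had a median of 1.75, and 3 of its 5 members rose adjusted over the list alone, with miR-429 at 2.61 ± 0.71, miR-200a at 1.94 ± 0.64 and miR-200b at 1.75 ± 0.62. The set was called higher (camera adjusted p = 1.42e-06), with adjusted p = 0.0908 with an estimated correlation. Of the month 6 libraries, replicates 1, 2 and 3 held 23370 to 44671 CPM of miR-200b and replicates 4 and 5, which stand apart, 3872 and 4792 CPM, within the month 4 range of 816 to 9504 CPM. The lowest of month 4 was replicate 5, and without it the median of the family was 1.60 (camera adjusted p = 0.00112). The miR-183-96-182 cluster had a median of 1.02 (camera adjusted p = 0.0329) and the let-7 family one of -0.37 (camera adjusted p = 0.00035), both with adjusted p = 0.245 with an estimated correlation, and the let-7 call was lost without the 5 libraries. Over all miRNAs 0 passed in edgeR, with 15 at an unadjusted p under 0.05 and 1 by DESeq2, but 6 without the 5 libraries that stand apart and 3 without the 7.

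The changes from day 1 were shared by both tissues, which have no library in common. Of 313 miRNAs tested in both, 44 were higher at month 2 than at day 1 in both tissues, against 14.0 for independent calls, and 26 were lower in both, against 9.78 (Fisher's exact p = 1.59e-21 and 1.63e-10, across miRNAs). At month 6 these numbers were 66 against 21.3 and 47 against 16.3 (Fisher's exact p = 5.07e-38 and 1.49e-21), and 0 miRNAs were called in opposite directions at either age. miR-92a-3p, miR-150, let-7a-5p and miR-1343 rose, and miR-542-3p and miR-379-5p fell, at both ages in both tissues. Across miRNAs the log2 changes correlated at r = 0.842 (rho = 0.862) for month 2 and r = 0.850 (rho = 0.857) for month 6, but at r = -0.0396 (rho = 0.0680) from month 2 to month 4 and r = 0.0816 (rho = 0.182) from month 4 to month 6. miRNAs are not independent replicates. Both ages were compared with the same day 1 libraries, so the overlaps at month 2 and month 6 are not independent of each other. The labels do not say whether both tissues of an age came from the same goats. A preparation that differed for the day 1 libraries, left open below, could also give shared changes.

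**Figure D3:**
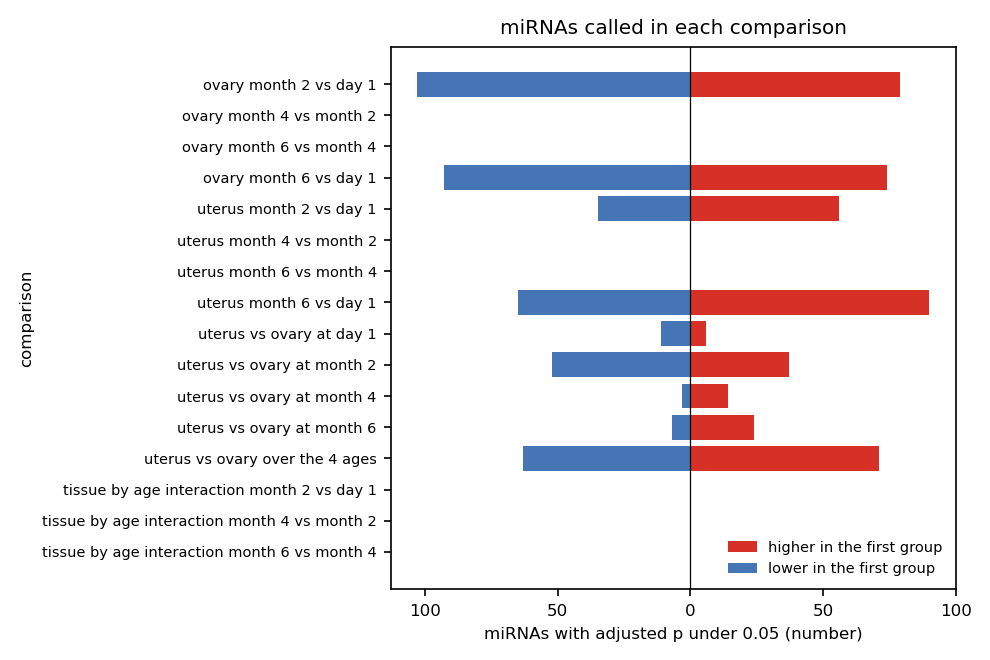
Number of miRNAs with an adjusted p under 0.05 in each of the 16 comparisons, to the right those higher and to the left those lower in the group named first. Within a tissue, the 4 comparisons with day 1 hold 91 to 182 calls and those between later ages hold 0, as do the 3 interaction terms.

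Over the 4 ages, the uterus was set apart from the ovary by muscle miRNAs and the ovary by miR-202. miR-206 was 17.4-fold higher in uterus (4.12 ± 0.34, adjusted p = 2.7e-12), miR-1 was 2.60 ± 0.33 higher and miR-133a-3p 2.17 ± 0.24. Of 6 striated muscle miRNAs 5 were higher, also adjusted over the list alone (camera adjusted p = 8.61e-07, and adjusted p = 0.00477 with an estimated correlation). miR-202-5p, known from gonads, had 99479 counts in the 20 ovary libraries and 37 in the 20 uterus libraries, a ratio of 2816 in shares of counts (counting interval 2043 to 4000). Ovary day 1 replicate 4 alone held 58944 of these counts, and without it the ratio was 1212 (880 to 1722). miR-202-3p had 5837 and 1 counts, a ratio of 6114 (1097 to 241547), the 1 count being from uterus month 4 replicate 2, without which only a lower bound is left. Of 7 gonad and granulosa cell miRNAs 4 were lower in uterus, also adjusted over the list alone: both arms of miR-202, miR-378-3p (-1.05 ± 0.26) and miR-383 (-1.11 ± 0.36), the last call being lost without the 7 doubted libraries (camera adjusted p = 7.34e-05, and adjusted p = 0.000902 with an estimated correlation).

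HOX-embedded miRNAs, which follow body position, were higher in uterus in 5 of 6 members, with miR-196b at 3.29 ± 0.66 (4.25 without ovary month 4 replicate 2), miR-10a-3p at 1.73 ± 0.35 and miR-10a-5p at 1.55 ± 0.37 (camera adjusted p = 0.00477, and adjusted p = 0.0615 with an estimated correlation). Epithelial miRNAs were higher in uterus: 4 of 5 of the miR-200 family, with miR-200a at 2.09 ± 0.56, miR-141 at 2.85 ± 0.64 and miR-429 at 1.74 ± 0.58 (camera adjusted p = 0.00448), and 3 of 3 of the miR-183-96-182 cluster, with miR-182 at 1.54 ± 0.33 (camera adjusted p = 0.0227). Both had adjusted p = 0.245 with an estimated correlation. In the miR-143/miR-145 cluster 3 of 4 members were higher, with miR-145-5p at 0.94 ± 0.15 (camera adjusted p = 0.0202, and adjusted p = 0.222 with an estimated correlation). The miR-424/miR-503 cluster was lower in 4 of 6 members, with miR-424-3p at -1.63 ± 0.23 and miR-450-5p at -1.26 ± 0.19 (camera adjusted p = 0.00332, and adjusted p = 0.169 with an estimated correlation). In the DLK1-DIO3 cluster 13 of 46 members were higher and 2 lower, with miR-369-3p at 1.42 ± 0.22 (camera adjusted p = 0.0106, and adjusted p = 0.490 with an estimated correlation). All counts of these 6 lists were the same adjusted over the list alone.

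miR-9-5p, known from neurons, was 2.61 ± 0.22 higher in uterus and miR-9-3p 2.25 ± 0.32, while miR-128-3p and miR-129-3p were lower, which made 2 and 2 of 7 neural members (camera adjusted p = 0.323). Of 7 leukocyte miRNAs miR-146a was higher and miR-155-5p (-1.07 ± 0.23) and miR-146b-5p (-0.67 ± 0.22) were lower, with a median of 0.19, a mean of -0.01 and camera adjusted p = 0.679. The other lists were not called: in the let-7 family 1 of 9 members was lower (camera adjusted p = 0.447), in the miR-17-92 cluster and its paralogs 3 of 12 (0.151), in the miR-29 family 0 of 5 were called (0.323), in miR-34/miR-449 0 of 7 (0.560), and in miR-199/miR-214 2 of 5 were higher (0.447). Adjusted over the list alone, 0 let-7 members and 2 of the miR-17-92 cluster and its paralogs were lower. Of 2 endothelial miRNAs 0 and of 2 red blood cell miRNAs 1 was called, the liver miRNA miR-122 was at -0.46, and no pluripotency miRNA was in the table. Of 350 miRNAs 134 were called, 71 higher and 63 lower in uterus (66 and 76 with DESeq2 size factors), 125 without the 5 libraries that stand apart and 147 without the 7 doubted libraries.

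**Figure D4:**
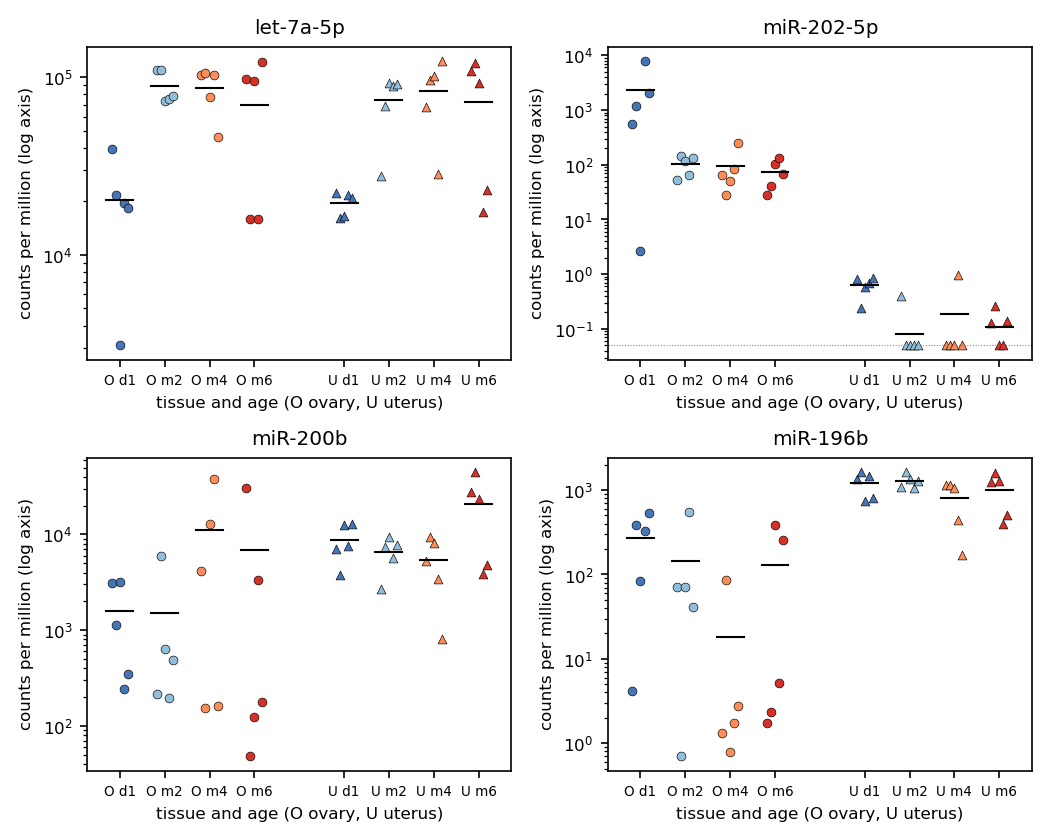
CPM (log axis) of let-7a-5p, miR-202-5p, miR-200b and miR-196b in each library, by tissue and age; points are libraries, bars are group means (n = 5), and libraries with no count are drawn on the dotted line. Ovary miR-202-5p had a mean of 2316 CPM at day 1, where single libraries held 2.61 to 7818 CPM, and 102 CPM at month 2, against at most 0.638 CPM in uterus groups, and ovary miR-200b spanned 154 to 38355 CPM at month 4.

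At day 1 the newborn uterus already differed from the ovary in miR-206 (4.34 ± 0.69, 83.7 ± 28.4 against 3.45 ± 1.97 CPM, higher in all 5 libraries) and in miR-221-5p (1.81 ± 0.35). miR-202-5p had 24 counts in uterus and 90286 in ovary, a ratio of 3560 (2392 to 5556), but 1519 (1021 to 2371) without ovary day 1 replicate 4. miR-202-3p had 0 and 575 counts, 292 of them in that library. Ovary day 1 replicate 3 held only 2.61 CPM of miR-202-5p, against 27.5 to 7818 CPM in the other ovary libraries. The miR-424/miR-503 cluster was lower in 3 of 6 members, 5 adjusted over the list alone, with miR-424-3p at -2.25 ± 0.47 (camera adjusted p = 5.3e-07, and adjusted p = 0.0108 with an estimated correlation). Striated muscle miRNAs (median 1.65, 1 of 6 higher, 4 adjusted over the list alone) had camera adjusted p = 7.06e-06, and gonad miRNAs (2 of 7 lower, 3 adjusted over the list alone) 0.00627, and adjusted p = 0.0108 and 0.0132 with an estimated correlation. Of 350 miRNAs 17 were called, 6 higher and 11 lower, but 29 with library totals (19 and 10), 37 by DESeq2, 27 without ovary day 1 replicate 3, 26 without the 5 libraries and 60 without the 7.

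At month 2 striated muscle miRNAs stood higher in uterus in 5 of 6 members, also adjusted over the list alone, with miR-206 at 4.33 ± 0.68 and miR-1 at 3.57 ± 0.68 (camera adjusted p = 5.54e-05, and adjusted p = 0.0265 with an estimated correlation). HOX-embedded miR-10a-5p was 2.93 ± 0.77 higher, and its list, with 2 of 6 members higher and 4 adjusted over the list alone, was called (camera adjusted p = 0.00476, and adjusted p = 0.0354 with an estimated correlation). miR-9-5p was 3.00 ± 0.46 higher, miR-218 3.00 ± 0.74, a call lost without uterus month 2 replicate 1 (1.73, with miR-1 then at 2.89), and miR-378-3p (-2.39 ± 0.54), miR-296-3p (-2.30 ± 0.50) and miR-148b-3p (-2.18 ± 0.32) were lower. miR-202-5p had 3 and 3259 counts, a ratio of 1288 (440 to 6248), all 3 being from uterus month 2 replicate 1. miR-202-3p, with 0 and 2220, was at least 877-fold lower against the floor of 3 counts, and at least 713-fold by the exact counting interval. Of 350 miRNAs 89 were called, 37 higher and 52 lower, 104 without the 5 libraries and 100 without the 7. With DESeq2 size factors 51 were higher and 44 lower.

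At month 4 the striated muscle miRNAs were again higher in uterus, with miR-206 at 3.51 ± 0.66, miR-1 at 2.90 ± 0.66 and miR-133a-3p at 2.83 ± 0.49, in a list with 5 of 6 members higher, also adjusted over the list alone (camera adjusted p = 1.05e-07, and adjusted p = 0.00319 with an estimated correlation). The largest difference in favour of uterus was that of the HOX-embedded miR-196b, 5.37 ± 1.45 higher, with 796 ± 461 against 18.3 ± 37.2 CPM, but the call was lost without ovary month 4 replicate 1, 3, 4 or 5 or uterus month 4 replicate 3, and the value was 9.23 without ovary month 4 replicate 2. Without ovary month 4 replicate 4 miR-1 was at 2.27. miR-202-5p had 6 and 3178 counts, a ratio of 558 (256 to 1521), but 321 (147 to 876) without ovary month 4 replicate 5, and all 6 were from uterus month 4 replicate 4. miR-202-3p had 1 and 1642, a ratio of 1729 (310 to 68348), the 1 count being from uterus month 4 replicate 2, without which only a lower bound is left. Of 350 miRNAs 17 were called, 14 higher and 3 lower, 26 by DESeq2, 13 without the 5 libraries and 26 without the 7. Leaving out ovary month 4 replicate 1 gave 10, replicate 5 gave 11, uterus month 4 replicate 3 gave 10, and fitting only the groups compared gave 9. With DESeq2 size factors 11 were higher and 6 lower, with library totals 8 and 5, and the median of all miRNAs moved from 0.13 to -0.05 and -0.11.

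At month 6 miR-206 (4.31 ± 0.68) and miR-9-5p (3.96 ± 0.48, 1842 ± 1336 against 103 ± 34.1 CPM, higher in all 5 libraries) were the largest differences in favour of uterus, miR-206 being at 3.14 without uterus month 6 replicate 1 and at 5.602 without ovary month 6 replicate 1. miR-202-5p had 4 and 2756 counts, a ratio of 710 (277 to 2609), but 1131 (313 to 9342) without uterus month 6 replicate 2. miR-202-3p, with 0 and 1400, was at least 481-fold lower in uterus against the floor of 3 counts, and at least 391-fold by the exact counting interval. The DLK1-DIO3 cluster was higher in 7 of 46 members, 15 adjusted over the list alone, with a median of 0.92 (camera adjusted p = 2.1e-08, and adjusted p = 0.133 with an estimated correlation). Gonad miRNAs were lower in 3 of 7 members, 4 adjusted over the list alone (camera adjusted p = 2.49e-05, and adjusted p = 0.000442 with an estimated correlation). Without the 5 libraries that stand apart the calls of miR-490 (2.65 ± 0.65), miR-1 (2.11 ± 0.64) and miR-383 (-2.44 ± 0.75) were lost. Of 350 miRNAs 31 were called, 24 higher and 7 lower, but only 7 without the 5 libraries, and 26 without the 7. The count was 12, 15 and 19 without ovary month 6 replicates 2, 3 and 5, and 15, 17, 17 and 18 without uterus month 6 replicates 1, 2, 3 and 5. With DESeq2 size factors 13 were higher and 8 lower, with library totals 27 and 3, with no filter 20 were called and with only the groups compared 14.

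The interaction terms asked whether an age change differed between the tissues, and no single miRNA was called in the edgeR fit of all groups. For month 2 against day 1 that count of 0 became 5 with only the groups compared in the fit and 2 with the stricter filter. For month 2 against day 1 the smallest p was that of miR-148b-3p (-1.83 ± 0.43, adjusted p = 0.0532), for month 4 against month 2 that of miR-195-3p (1.99 ± 0.54, adjusted p = 0.149), and for month 6 against month 4 that of miR-9-5p (1.97 ± 0.60, adjusted p = 0.814), each named after its value was seen. At the last step the DLK1-DIO3 cluster had a median interaction of 0.59 (camera adjusted p = 6.57e-11, and adjusted p = 0.178 with an estimated correlation) and the miR-200 family one of 2.42 (camera adjusted p = 0.00125, and adjusted p = 0.261 with an estimated correlation). The edgeR counts were 0, 0 and 0, with 47, 57 and 13 at an unadjusted p under 0.05, and 12, 0 and 0 by DESeq2. Without the 5 libraries they were 4, 0 and 1, and without the 7 libraries 0, 0 and 2. Leaving out single libraries gave up to 1 for the first step (without ovary day 1 replicate 4 or uterus month 2 replicate 1) and up to 3 for the last (3 without ovary month 6 replicate 1, and 1 without uterus month 6 replicate 5). The median of all miRNAs moved with the scaling, from 0.06 to 0.32 with DESeq2 size factors at the first step and from 0.26 to -0.11 at the next.

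Across the 16 comparisons 53 of 236 list tests were called at the preset correlation and 12 with an estimated correlation. These 12 were the miR-29 family in ovary from month 2 to month 4, striated muscle miRNAs at day 1, month 2, month 4 and over the ages, gonad miRNAs at each age and over the ages, the miR-424/miR-503 cluster at day 1 and HOX-embedded miRNAs at month 2. The gonad list holds both arms of miR-202, miR-202-5p at -9.89 and miR-202-3p at -10.6 over the ages. Its test was not repeated without them, so its calls may rest mainly on this hairpin. No named miRNA with a call changed direction with either other scaling. Only calls were followed, for which a reversal was unlikely from the start, and named miRNAs without a call were not checked.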

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

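The searches below were run on every group and list alike, and the libraries and lists named were picked out after their values were seen, so these are tests and not predictions. Dixon's ratio over 31 quantities and 248 groups of 5 picked out 22 libraries' values, where 12.4 are expected by chance. Ovary day 1 replicate 3, uterus month 2 replicate 1 and uterus month 4 replicate 5 had 4 each.

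In ovary day 1 replicate 3, miR-143-3p took 73.3% of the counts (12.4% to 22.7% for the most abundant miRNA of the other 4) at 733103 CPM (88444 to 156515), the miR-143/miR-145 cluster of smooth muscle had a mean log2 CPM of 13.35 (10.82 to 11.46), and let-7i-5p stood at 10090.0 CPM (49503 to 56644). Log2 CPM takes in the TMM factor, which was 0.389 in this library and 0.972 to 1.26 in the other 4. Part of the gap in the cluster mean therefore comes from the scaling. In uterus month 2 replicate 1, miR-143-3p stood at 245780 CPM (84565 to 126254) and miR-148a-3p at 74334 CPM (9479 to 14480), with mean log2 CPM of 6.71 for striated muscle miRNAs (5.51 to 5.83) and 11.07 for miR-199/miR-214 (10.56 to 10.68). In uterus month 4 replicate 5, mean log2 CPM was 4.36 for the miR-200 family (7.70 to 8.29), 4.14 for striated muscle miRNAs (5.71 to 6.10) and 2.75 for the miR-424/miR-503 cluster (4.340 to 4.601), and let-7i-5p was at 62546 CPM (15934 to 23175).

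The most abundant miRNA took 18.2% of counts in ovary month 4 replicate 5 (10.2% to 11.6% in the others), where miR-143-3p was at 181792 CPM (51452 to 81395), and 18.7% in ovary month 6 replicate 4 (9.83% to 12.2%). Ovary month 4 replicate 2 held 334 detected miRNAs (360 to 365) and ovary month 6 replicate 3 held 344 (362 to 369). The miR-200 family had a mean log2 CPM of 6.92 in ovary month 2 replicate 2 (3.37 to 3.95), and the miR-183-96-182 cluster 2.13 in ovary month 2 replicate 5 (3.12 to 3.49). Gonad and granulosa cell miRNAs had 6.31 in uterus month 2 replicate 2 (6.56 to 6.64), let-7f-5p 59559 CPM in uterus day 1 replicate 4 (44713 to 47819) and miR-148a-3p 70499 CPM in uterus month 4 replicate 4 (10967 to 22606).

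Some lists changed differently in the tissues by camera at the preset correlation, and none did with an estimated correlation. From day 1 to month 2, the DLK1-DIO3 cluster had adjusted p = 0.025002 (adjusted p = 0.519 with an estimated correlation) and HOX-embedded miRNAs 0.0356 (0.314), the latter lost with DESeq2 size factors. From month 2 to month 4, the miR-200 family and the miR-34/miR-449 family both had adjusted p = 0.00610 and the miR-183-96-182 cluster 0.0262, each with adjusted p = 0.671 with an estimated correlation. From month 4 to month 6, the miR-200 family had adjusted p = 0.00125 (0.261 with an estimated correlation), the miR-183-96-182 cluster 0.00264 (0.241), the miR-34/miR-449 family 0.00763 (0.453) and the DLK1-DIO3 cluster 6.57e-11 (0.178). Of the miR-34/miR-449 calls, the earlier was lost without the 7 doubted libraries and the later with library totals alone.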

How the results depend on the processing

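Counts of calls under other settings are given below where they differed from those of the edgeR analysis by more than 1.5 times. Those with the replicate number as a block are given only in this section. For ovary month 4 against month 2, with 0 called, DESeq2 gave 1, the fit of only the groups compared 1, and the removal of the 7 doubted libraries 2. For ovary month 6 against month 4, with 0 called, DESeq2 gave 1. For uterus month 2 against day 1, with 91, no filter gave 137, DESeq2 143, only the groups compared 141, removal of the 5 libraries that stand apart 141 and of the 7 libraries 209. For uterus month 4 against month 2, with 0, the stricter filter gave 1, DESeq2 12 and the replicate block 3. For uterus month 6 against month 4, with 0, DESeq2 gave 1, removal of the 5 libraries 6 and of the 7 libraries 3. For uterus against ovary at day 1, with 17, library totals gave 29, DESeq2 37, removal of the 5 libraries 26 and of the 7 libraries 60. At month 4, with 17, DESeq2 gave 26, the block 11, only the groups compared 9 and removal of the 7 libraries 26. At month 6, with 31, no filter gave 20, only the groups compared 14 and removal of the 5 libraries 7. For the interaction of month 2 against day 1, with 0, the stricter filter gave 2, DESeq2 12, only the groups compared 5 and removal of the 5 libraries 4. For that of month 6 against month 4, with 0, removal of the 5 libraries gave 1 and of the 7 libraries 2. Of the 53 list calls, 12 held with an estimated correlation.

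The let-7 family in ovary from month 4 to month 6 reversed, from a mean of -0.37 to 0.0905 without the 5 libraries (adjusted p = 0.119) and 0.116 without the 7 libraries (adjusted p = 0.0842). Of 426 results on called miRNAs none reversed. Between 7 and 49 became weaker with each setting over all libraries or without the doubted ones, and not every miRNA could be tested in each. All 426 were calls of the edgeR analysis, so a reversal was unlikely from the start, and miRNAs without a call were not followed. With single libraries left out, 5334 values kept their call and 786 became weaker.

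With single libraries left out, the counts for ovary were 177 to 184 for month 2 against day 1, 0 to 1 for month 4 against month 2, 0 to 0 for month 6 against month 4 and 154 to 183 for month 6 against day 1. For uterus they were 61 to 188, 0 to 1, 0 to 0 and 135 to 158. For uterus against ovary they were 14 to 27 at day 1, 64 to 91 at month 2, 10 to 23 at month 4, 12 to 35 at month 6 and 125 to 157 over the 4 ages, and for the interactions 0 to 1, 0 to 0 and 0 to 3.

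With the replicate number as a block, the counts within ovary were 178, 0, 0 and 158, and within uterus 104, 3 and 0 in the same order, with 83 higher and 62 lower for month 6 against day 1. Between the tissues they were 13, 76, 11, 23 and 134, and 0 for each interaction. Profiles of the same number in different groups correlated between -0.540 and 0.634 after group means were taken out, and at most 3 of 5 libraries fitted best with their own number. That highest case was uterus month 2 with month 4, with correlations of -0.0704 to 0.507. The labels state no pairing and in no case did all 5 numbers deviate together, so libraries were treated as independent. The numbers start again at each age. Whether an ovary and a uterus of the same age and number share a goat stays open, and such pairs correlated between -0.395 and 0.353. The cause was not tested.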

Other observations

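In ovary from day 1 to month 2, 8 hairpins had both arms called in opposite directions. Besides miR-202 and miR-424 they included miR-106b (5p -2.37, 3p 1.82), miR-30b (5p -1.99, 3p 1.84), miR-455 (5p -1.60, 3p 1.91) and let-7a (5p 1.97, 3p -1.54). Without miR-202 these were 7 of 37 hairpins with both arms called, against 3 of 29 in ovary at month 6, and in uterus 1 of 11 at month 2 and 1 of 25 at month 6, each against day 1, while between the tissues over the 4 ages 0 of 20 were opposite. In ovary, the HOX-embedded miR-196b ran from 0.699 to 543 CPM among the 5 libraries of month 2 and from 1.74 to 388 CPM among those of month 6, while the uterus libraries held 169.7 to 1628 CPM. The ciliated epithelium miRNA miR-34c ran from 2.89 to 5967 CPM in ovary at month 4 and from 0.505 to 2525 CPM at month 6.

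For the patterns below, the arm test of the 5 libraries, their likeness to day 1, the miR-183-96-182 test, the depth test and the splits were set down before their results were seen. The others were chosen after the result was seen. All are tests and not predictions, and a biological difference of age or tissue stays open throughout.

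The profile of day 1 differed from that of later ages in both tissues. A library preparation or sequencing that differed between day 1 and later ages could give this, since it would act on single sequences and not on transcripts: the changes of the 5p and 3p arms correlated at rho = 0.446 (0.255 to 0.597) over 98 hairpins in ovary and 0.357 (0.153 to 0.532) over 102 in uterus for month 2 against day 1, against a lowest value of 0.568 (0.405 to 0.687) between the tissues at single ages, and at 0.578 and 0.525 for month 6 against day 1, so the overlapping intervals leave this open. Transcription as the whole cause would move both arms alike. In ovary at month 2 the median difference between arms was 1.23 (0.862 to 1.40), against at most 0.603 (0.428 to 0.829) between the tissues. The changes were larger as well, with a median absolute mean of both arms of 0.966 against 0.386 to 0.819, and the difference was not scaled to them. It therefore argues only weakly against that cause in ovary. In uterus the median difference between arms was 0.898 (0.681 to 1.08). Its lower end also lay above 0.603, but its interval overlapped that of 0.428 to 0.829, which leaves that cause open there. The miR-143-3p excess of ovary day 1 replicate 3 as the cause is argued against, as 177 miRNAs were called without that library. A hypothesis to be tested is that arm choice or miRNA decay changes after birth, which spike-in small RNAs or a repeat with all ages in the same preparation would separate from preparation.

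The 5 libraries that stand apart may have had exchanged labels. Their lowest let-7b-3p level was 1198 CPM against at most 419 CPM in any other library, which argues against an exchange with the 35 others as the cause. That level was among the values that set the 5 apart. An exchange among the 5 would leave it as it is, so such an exchange stays open. A preparation shared by the 5 might show in their arms: the median arm correlation of their deviation was rho = 0.0955, against 0.348 in the 35 others, which is itself too low for the test to decide. Between the ovary and the uterus libraries of the 5, these deviations correlated at Pearson's r = 0.353 to 0.744 (median 0.596). The 5 were picked by their values and other libraries were not compared in this way, so it decides nothing on the cause. A preparation shared with day 1 gave a median rho of 0.263 with the day 1 change of the other tissue, which leaves it open. Repeat libraries from the same RNA would test this.

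The miR-200 family varied widely among ovary libraries, and pieces holding different amounts of epithelium could give this. After the median of each age was taken out, its mean level followed the miR-183-96-182 cluster (rho = 0.787, permutation p adjusted over 4 tests = 0.000200, n = 20) and the ciliated miR-34/miR-449 family (rho = 0.924, permutation p adjusted over 4 tests = 4e-05). Without the 2 farthest libraries Pearson's r was 0.808 and 0.859, against 0.877 and 0.906 with all 20. Library depth is argued against (rho = -0.205, permutation p = 0.385). HOX-embedded miRNAs did not follow it (rho = -0.272, adjusted permutation p = 0.324). Histology of the same ovaries, or staining for oviduct epithelium, would test the hypothesis that oviduct or surface epithelium was taken along.

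Whether chance can be excluded was asked with 100 splits of the same libraries per comparison, by how many called at least as many miRNAs as the real groups, the real split included. In ovary this held for 1 split for month 2 against day 1 (182 called, highest other 41) and for 1 for month 6 against day 1 (167, highest other 49). In uterus it held for 2 for month 2 against day 1 (91, highest other 108) and 1 for month 6 against day 1 (155, highest other 34). For the steps from month 2 to month 4 and from month 4 to month 6, with 0 called, it held for all 100 in each tissue by construction, so the splits decide nothing there; the highest others were 0 and 15 in ovary and 1 and 82 in uterus. Between the tissues it held for 1 at day 1 (17, highest other 11), 1 at month 2 (89, highest other 14), 1 at month 4 (17, highest other 15) and 1 over the 4 ages (134, highest other 28). At month 6 it held for 5 (31, highest other 95), so chance is not excluded there. For the interactions, with 0 called, it held for 100 each, again by construction, with highest others of 137, 2 and 86. Splits called far more than the real groups in uterus from month 4 to month 6 (82) and between the tissues at month 6 (95). These point to a structure of the samples that does not follow age or tissue. The interaction splits exchanged ages within each tissue, so an age change shared by the tissues can appear there as an interaction. Their highest counts therefore do not show such a structure.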
